A study of Rattus norvegicus with 14 samples.

How the data were processed

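RNA was measured on 14 Affymetrix arrays of primary rat striatal neuron cultures kept for 6 weeks in vitro, per the labels. There were 4 groups: 3 arrays of uninfected cells, 3 of cells infected with a lentivirus that carries GFP, 4 of cells infected with a virus for the first 171 residues of huntingtin with 19 glutamines (Htt171-19Q), and 4 with the same fragment and 82 glutamines (Htt171-82Q). Infection took place 6 weeks before collection, per the labels. Replicates were numbered within a group in the order of deposit, and these numbers only name an array. The titles of 2 of the 4 arrays in each Htt171 group carry a suffix, a point and the digit 2, which the labels do not explain. No control array carries it. It was treated as a possible batch.

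The deposited values are on a log2 scale, with 1 value per probe set. The scale was read from the values, which run from 3.1 to 13.78. Array medians of the deposited values lie between 6.02 and 6.07. Background correction, normalization and summary method are not given in the sources used here. The values were used as deposited, with no further scaling and no filter on dim probe sets. Of 15923 probe sets, 57 control probe sets were left out of the tests and 15866 were tested. The probe table, made from the platform annotation, paired 12783 of the tested probe sets with 1 gene and 312 with several, and did not list 2771 of them. The gene table gave the same symbol for each identifier it held, and probe sets with several genes were not named.

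Each of the 6 comparisons between groups came from 1 limma fit (limma 3.58.1, R 4.3.3) over all 14 arrays, with a mean per group and an empirical Bayes variance. Tests were two-sided, and Benjamini-Hochberg adjustment ran over the probe sets of 1 comparison. A probe set was called at an adjusted p under 0.05. Errors of fold changes are standard errors from this fit, and errors of group means are SDs over arrays. For gene lists and named genes, a gene stood for its probe set with the highest mean value over the 14 arrays. The 22 lists were tested with camera, with a preset correlation of 0.01 between genes, adjusted over the lists of 1 comparison. Camera with an estimated correlation and the directional fry test were run beside it. For counts adjusted over the list alone, the adjustment ran over the members of that list only. Measures of single values were compared with exact permutation tests.

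The groups, the comparisons, the lists, the rule for named genes and the alternatives, other than leaving out arrays by title suffix, were fixed before the data were examined. The rule took genes whose higher group lay above the median level, which passed adjusted p 0.05 and whose arrays did not overlap between the groups. It named the 12 largest rises and 12 largest falls of Htt171-82Q against Htt171-19Q and 5 of each for every other comparison. Where fewer passed, genes with the smallest unadjusted p filled up to 5 and are said not to pass. Up to 4 members with the smallest p were named from each list described, and rat Htt was always included.

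The fit was tested on simulated data with the means and spreads of the 15866 probe sets, for Htt171-82Q against Htt171-19Q. The 200 changed probe sets were all drawn from those with a mean above the median level, so the recovery does not cover dim probe sets. It recovered 84% of the changes of 0.5 and 96% of those of 1 on the log2 scale, with 8 false calls among 188. Camera gave 1.37e-26 as the p-value of a simulated list of 30 genes shifted by 0.3, and 0.632 for an unshifted list. The simulated noise was independent between genes. It therefore does not show how the preset correlation holds for lists of correlated genes, such as the proteasome, with an estimated correlation of 0.266.

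Alternatives were quantile normalization, centring each array on its median, leaving out dim probe sets, fitting only the 2 groups compared, an intensity trend with robust variances, array weights, the title suffix as a covariate, the mean over a gene's probe sets, the other list tests, and leaving out each array in turn. Genes read by several probe sets can give different values, and 8 of the 41 such genes among those the rule took had a probe set of opposite sign between Htt171-82Q and Htt171-19Q. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.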

Results

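Gene expression was profiled in primary cultures of rat striatal neurons. The cultures were left uninfected or were infected with lentivirus for GFP, for an N-terminal huntingtin fragment with 19 glutamines, or for the same fragment with 82 glutamines. The uninfected and GFP groups held 3 arrays each and the Htt171-19Q and Htt171-82Q groups 4 each. Values of 15866 probe sets are on a log2 scale as deposited. Within groups, arrays correlated at r between 0.9897 and 0.9976 across probe sets, which are not independent replicates, and no pair shared more than 10 identical values. The first principal component held 47.7% of the variance and set the 4 Htt171-82Q arrays, at 16.4 to 27.4, apart from the other 10, at -15.4 to 3.48. Among these, the Htt171-19Q arrays, at -5.68 to 3.48, all lay above the GFP and uninfected arrays, at -15.4 to -11.8. On the second component, 15.9% of the variance, arrays with the title suffix lay below the other arrays of their own group, at -18.8 and -12.9 against -2.32 and -2.6 in Htt171-19Q, and at -0.836 and -8.67 against 10.6 and 18.2 in Htt171-82Q.

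**Figure D1:**
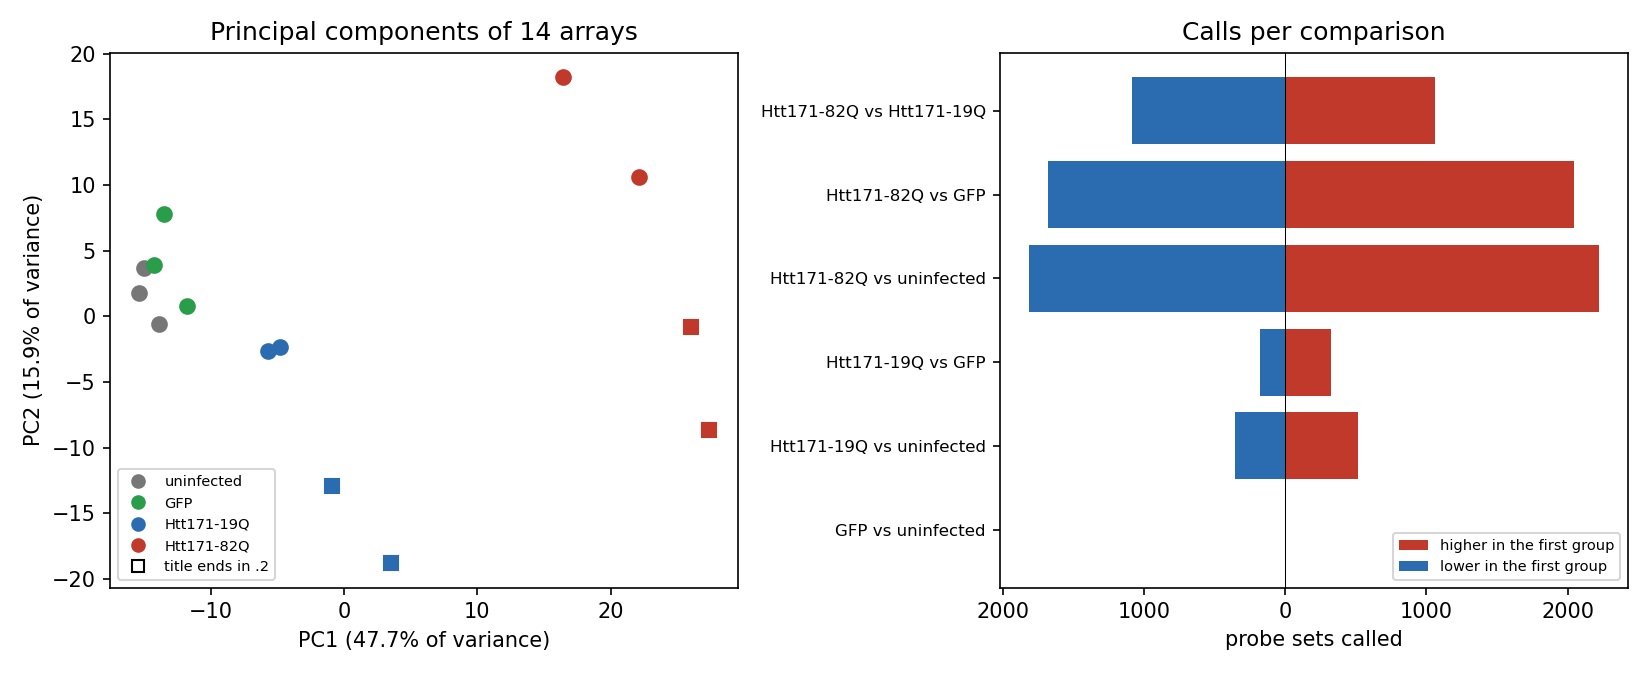
Left, scores of the 14 arrays on the first 2 principal components, coloured by group, with squares for titles that carry the suffix. Right, probe sets called higher (red) or lower (blue) in the first group of each of the 6 comparisons, from 4040 for Htt171-82Q against uninfected to 2 for GFP against uninfected.

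The comparison of the 2 fragments asks what the longer glutamine repeat changes when fragment and virus are present in both arms. Somatostatin (Sst, probe set 1367762_at) was 7.22 ± 0.17 (SD, n = 4) in Htt171-82Q and 10.3 ± 0.29 in Htt171-19Q, so that it fell by 3.08 ± 0.12 (SE) on the log2 scale, an 8.46-fold difference (limma adjusted p = 2.06e-10). Neuropeptide Y (Npy, 1387154_at) fell by 2.54 ± 0.2 (adjusted p = 4.35e-07), and the serotonin receptor gene Htr2c (1376980_at) fell by 2.44 ± 0.13 (adjusted p = 1.29e-08). The opioid peptide precursor Penk fell by 2.07 ± 0.09. The striatum-enriched phosphoprotein gene Arpp21 fell by 2.28 ± 0.1, the guanylate cyclase subunit gene Gucy1a1 by 2.22 ± 0.07 and the cyclic nucleotide phosphodiesterase gene Pde2a fell by 1.9 ± 0.07. The other named falls were Wipf3, which fell by 2.26, Plcxd3, which fell by 2.18, Enc1, which fell by 2.11, Ngef, which fell by 1.99, and the calmodulin-binding Pcp4, which fell by 1.91.

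The largest rises were smaller than the largest falls. The copper-binding plasma protein gene Cp (1368418_a_at) was 8.82 ± 0.54 against 6.82 ± 0.36, a rise of 2.0 ± 0.22 (adjusted p = 1.23e-05). The protease inhibitor gene A2m rose by 1.98 ± 0.14 (adjusted p = 1.48e-07) and the intermediate filament gene Vim by 1.86 ± 0.2 (adjusted p = 1.37e-05). Gpnmb rose by 1.49, the small heat shock protein gene Hspb1 by 1.33, Hopx by 1.27, the corepressor gene Sin3b by 1.13 and Ramp2 by 1.11. Zfp207 rose by 1.10, Tmem176b by 1.08, LOC100912002 by 1.05 and S100a4 by 1.03. For each of these 24 genes, the 4 arrays of one group lay above the 4 of the other, as the rule for naming them required. Probe sets of lower mean level for some of these genes gave other values: -0.03 for Sin3b, 0.04 for Enc1, -0.03 for Wipf3 and -0.09 for Htr2c, none of them called, and -0.3 for Gucy1a1. A further probe set of Cp gave 2.85.

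**Figure D2:**
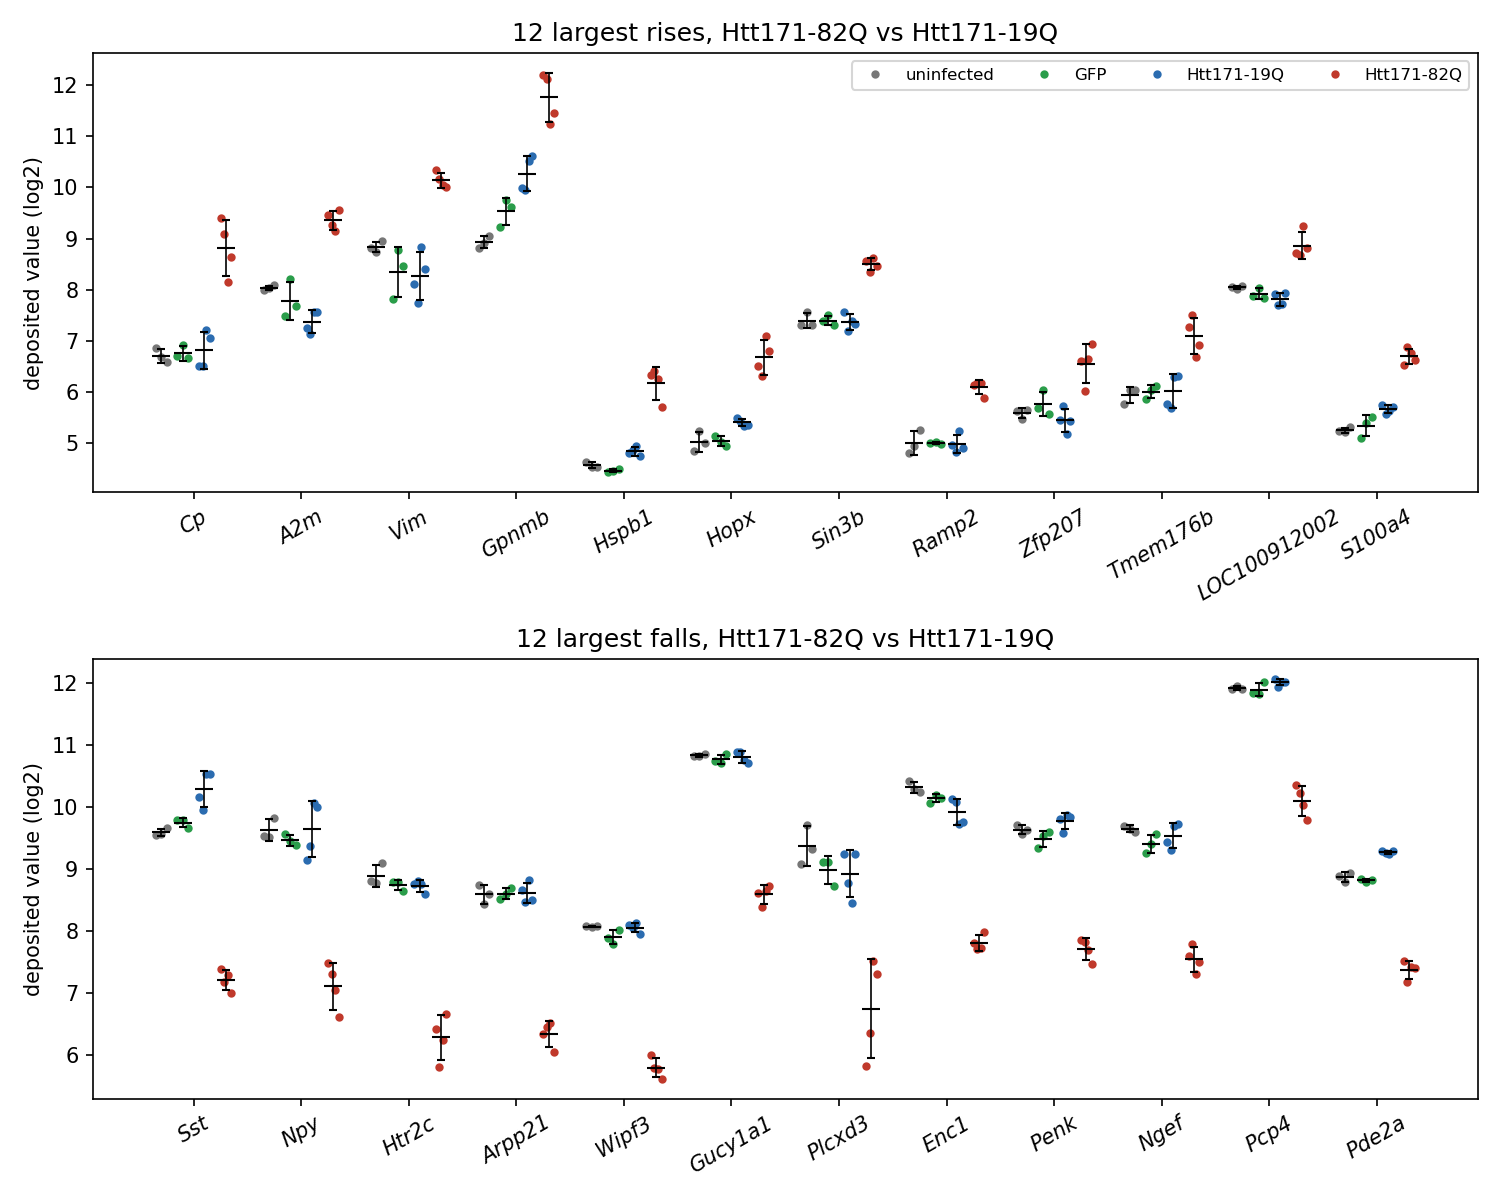
Deposited log2 values of the 12 genes with the largest rises and the 12 with the largest falls in Htt171-82Q against Htt171-19Q, in each array of the 4 groups. Points are arrays, long dashes are group means and bars are SDs. The rule took only genes whose Htt171-82Q arrays stand apart from those of Htt171-19Q, as for Sst at 7.22 against 10.3.

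Genes of striatal projection neurons were lower as a list. Of 35 measured, 17 fell, none rose and 18 were not called, with 19 lower when adjusted over the list alone (camera adjusted p = 2.81e-17, and 0.00123 with an estimated correlation). Besides Penk, Arpp21 and Pcp4, the G protein gene Rasd2 fell by 1.46 ± 0.08 (-0.22 on its other probe set). Of 38 potassium channel genes, 17 fell, or 21 adjusted over the list alone (camera adjusted p = 3.17e-11). Kcnc1 fell by 1.48, Kcnc2 fell by 1.45, Kcna1 fell by 1.45 and Kcns3 fell by 1.39. The other probe sets of Kcnc2 were not called, the lowest of them at -0.15. Of 26 neuropeptide and secretory granule genes, 15 fell, or 17 adjusted over the list alone (camera adjusted p = 6.42e-11), among them the growth factor gene Igf1, which fell by 1.15. In calcium signalling, 18 of 47 fell and 1 rose, with 19 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.98e-09). The calcium pump genes Atp2b2 and Atp2a2 fell by 0.97 and 0.92, the calcium sensor gene Ncald fell by 1.06 and the phospholipase gene Plcb1 fell by 0.90. Probe sets of lower mean level gave -0.25 for Atp2b2 and -0.24, -0.11 and -0.01 for Atp2a2, the last 2 not called.

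Synaptic lists were lower too. Of 16 GABA genes 7 fell, also adjusted over the list alone (camera adjusted p = 1.62e-06), including the receptor subunit gene Gabrb2, which fell by 1.22, and the GABA-synthesizing enzyme gene Gad1, which fell by 1.08. The vesicular transporter gene Slc32a1 fell by 0.53 and Gabbr2 fell by 0.59. Other probe sets of Gabrb2 (-0.14), Gad1 (-0.21) and Gabbr2 (-0.04) were not called. Of 35 genes of glutamate receptors and the postsynaptic density 10 fell, or 12 adjusted over the list alone (camera adjusted p = 8.91e-05). Nrgn fell by 1.42, Dlgap1 fell by 1.05, the AMPA receptor gene Gria3 fell by 1.04 and Dlg3 fell by 0.52. Other probe sets were not called for Gria3 (-0.04) and Dlg3 (-0.08 and 0.05), and those of Dlgap1 gave -0.63, called, and -0.09, not called. Of 32 synaptic vesicle genes 7 fell, also adjusted over the list alone (camera adjusted p = 9.89e-05), with Cplx1, which fell by 0.59, Rab3b, which fell by 0.55, Rims2, which fell by 0.40, and Snap25, which fell by 0.39. Pan-neuronal genes held 11 falls and 1 rise among 24, or 13 and 1 adjusted over the list alone (camera adjusted p = 5.02e-08). The neurofilament gene Nefl fell by 1.15 (-0.45 on its other probe set), Celf4 fell by 0.79, Reln fell by 0.74 and Thy1 fell by 0.47.

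Among targets of the RE1-silencing transcription factor, 7 of 23 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000165). Vgf fell by 0.91 and Scg2 fell by 0.60, whereas the calcium buffer gene Calb1 rose by 0.78. This list shared 6 genes with the synaptic vesicle list, 5 with the neuropeptide list and 4 with the pan-neuronal list. It is thus not separate evidence from those lists. Vgf and Scg2 are also on the neuropeptide list, and Calb1 on the calcium list. Cholesterol biosynthesis held 6 falls among 19, or 7 adjusted over the list alone (camera adjusted p = 0.000182). Pmvk fell by 0.68, Cyp51 fell by 0.62 (-0.16 on its other probe set, not called) and Tm7sf2 fell by 0.31. Sc5d fell by 0.28 on its brightest probe set, while its other probe set gave 0.43 with a call in the opposite direction. The call of Sc5d was lost without Htt171-19Q replicate 2 (adjusted p at most 0.534 over the alternatives). Of 30 immediate early genes 7 fell, also adjusted over the list alone, with Nr4a3, which fell by 1.5 (-0.15 on its other probe set), Dusp1, which fell by 1.26 (-0.05 on its other probe set), Jun, which fell by 0.55 (-0.51 and, not called, -0.17 on its other probe sets), and Egr1, which fell by 0.50. This list passed with camera's preset correlation (adjusted p = 0.00315) and did not pass with an estimated one (adjusted p = 0.0744 with an estimated correlation).

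Genes of protein folding and degradation were higher. The proteasome list held 18 rises among 31, or 23 adjusted over the list alone (camera adjusted p = 1.18e-10, and 0.0485 with an estimated correlation). Psma1 rose by 0.46, Psmb2 by 0.43, Psma4 by 0.40 and Psmd10 by 0.36. Of 31 heat shock and chaperone genes 12 rose, or 14 adjusted over the list alone (camera adjusted p = 1.63e-07). Hspb8 rose by 0.41, Ahsa1 by 0.36 and Dnajb1 by 0.35. Of 31 genes of the unfolded protein response 6 rose, also adjusted over the list alone (camera adjusted p = 0.00226), with the asparagine synthetase gene Asns at 0.70, Creld2 at 0.47, Pdia6 at 0.44 and the transcription factor gene Xbp1 at 0.34. Interferon and antigen presentation genes passed with camera's preset correlation (adjusted p = 0.00632) and not with an estimated one (adjusted p = 0.476 with an estimated correlation). The call was also lost without Htt171-82Q replicate 1 (adjusted p = 0.379), without dim probe sets (0.124) and without the suffixed arrays (0.526). Only B2m, 0.19, and Isg20, 0.28, rose among its 33 genes, also adjusted over the list alone. The call of B2m was lost without Htt171-19Q replicate 1 or 4 or Htt171-82Q replicate 1, and that of Isg20 without Htt171-19Q replicate 2 or 3 or Htt171-82Q replicate 1, 3 or 4 (adjusted p at most 0.276 and 0.377 over the alternatives).

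**Figure D3:**
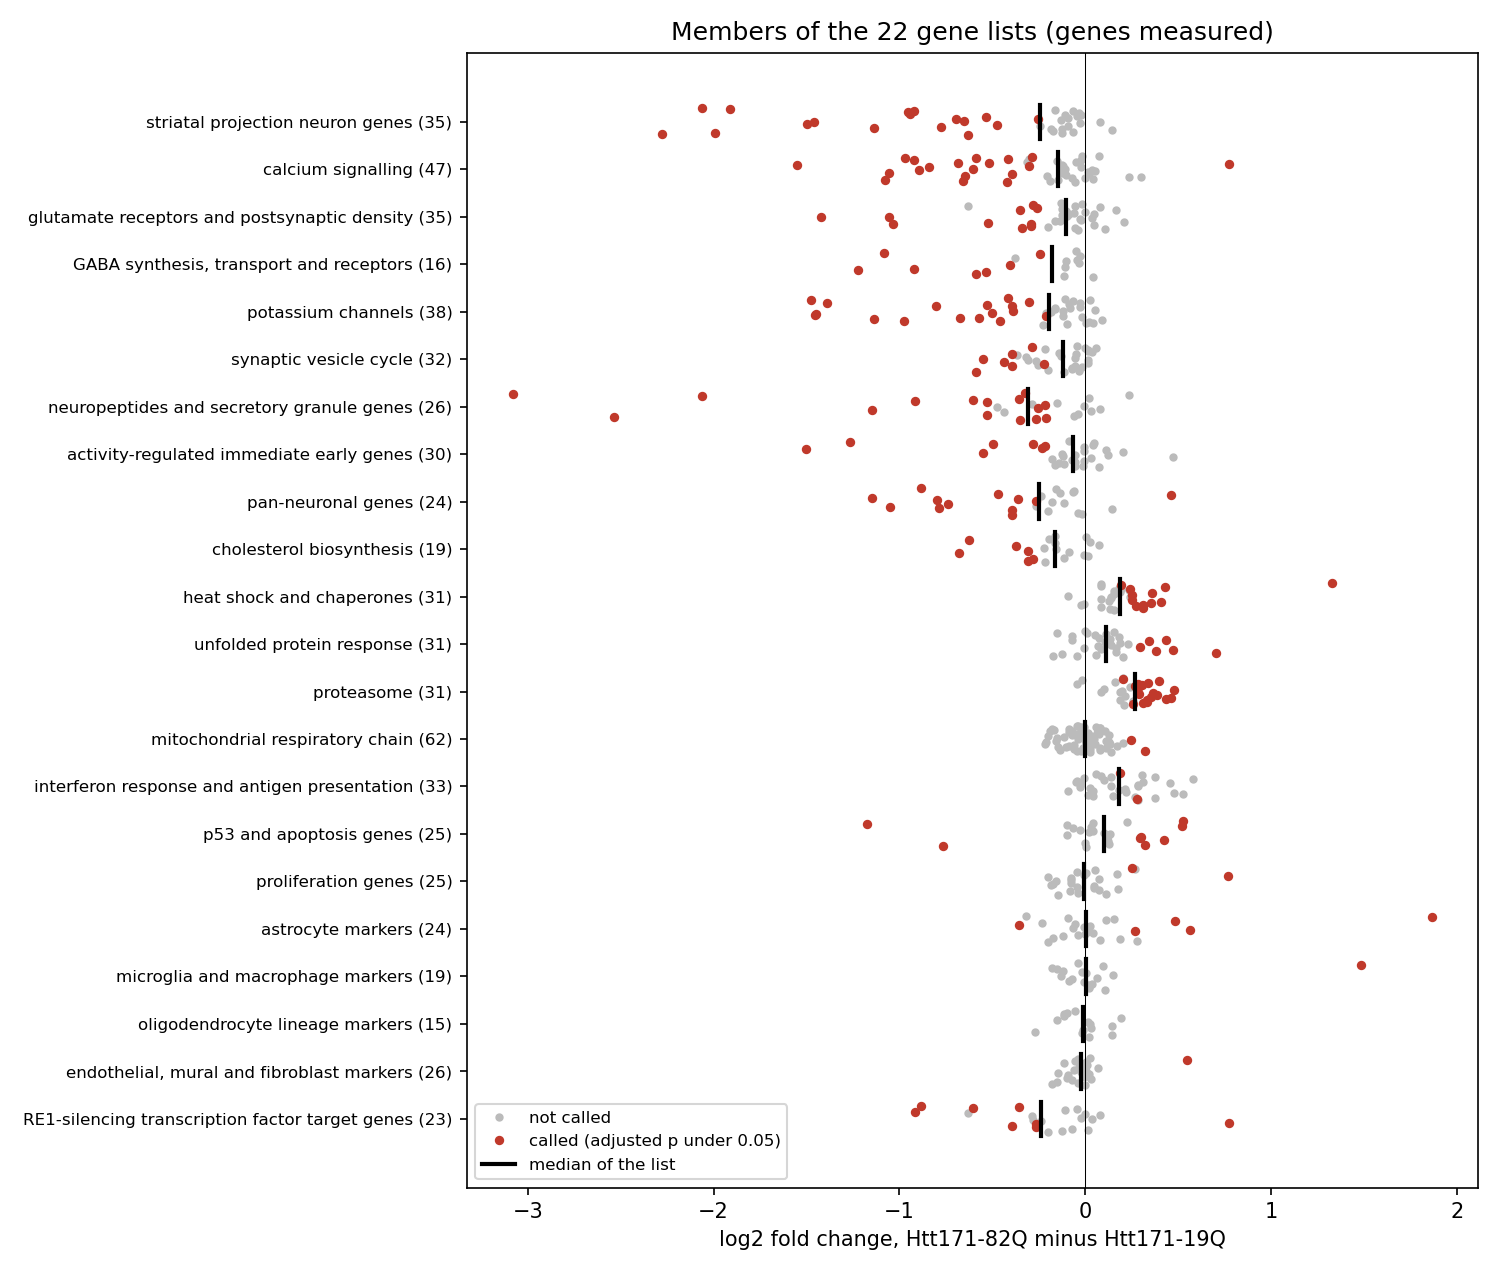
Log2 fold change of Htt171-82Q minus Htt171-19Q for each measured member of the 22 gene lists, with the number measured beside the name. Red points passed adjusted p 0.05, grey points did not, and black bars are list medians, from -0.305 for neuropeptides to 0.27 for the proteasome.

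The other 7 lists were not called. Respiratory chain genes had 2 rises among 62, Ndufa2 at 0.32 and Ndufs7 at 0.25, or 1 adjusted over the list alone, and a median of -0.00314 (camera adjusted p = 0.813). Without Htt171-82Q replicate 3 camera called this list lower (adjusted p = 0.0322). The call of Ndufs7 was lost without Htt171-19Q replicate 2 or Htt171-82Q replicate 3 (adjusted p at most 0.194 over the alternatives). The p53 and apoptosis list held 6 rises and 2 falls among 25, also adjusted over the list alone (camera adjusted p = 0.131): the kinase gene Plk2 fell by 1.18 and Bcl2l11 fell by 0.77 (0.04 and 0.05 on its other probe sets, not called), whereas Tnfrsf1a rose by 0.53 and Gadd45a by 0.52. Among 25 proliferation genes Ccnb1 rose by 0.77 and Pcna by 0.25, also adjusted over the list alone (camera adjusted p = 0.878). Their median was -0.00619 and their mean 0.0294, with camera's direction upward. Of 24 astrocyte markers 4 rose, among them Vim, Fabp7 at 0.56 and Gfap at 0.49, and Gjb6 fell by 0.35, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.5). Microglia markers gave 1 rise among 19, Gpnmb, also adjusted over the list alone (camera adjusted p = 0.959), with camera's direction downward and a median of 0.00545. None of 15 oligodendrocyte markers was called by limma, also adjusted over the list alone (camera adjusted p = 0.581). Endothelial, mural and fibroblast markers gave 1 rise among 26, Igfbp2 at 0.55, also adjusted over the list alone (camera adjusted p = 0.427).

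In all, 2148 probe sets (13.5%) were called between the 2 fragments, 1064 higher and 1084 lower in Htt171-82Q, of which 20 and 113 changed at least 2-fold. The share of higher calls, 49.5%, was 50.8% with quantile normalization, 54.7% with each array centred on its median, 52.9% without dim probe sets, 51.9% with array weights, 51.2% with the title suffix as a covariate, 50.8% without Htt171-19Q replicate 1 and 56.5% without Htt171-82Q replicate 2. Among lower shares were 44.6% without Htt171-82Q replicate 4 and 45% without Htt171-19Q replicate 4. Arrays of the 2 groups did not overlap for 14.6% of all probe sets, where chance gives 2.86%. A fit of only these 2 groups called 1374, of which 591 were higher (43%) and 783 lower. With only the suffixed arrays of both groups, 2 against 2, the count was 1185 (454 higher and 731 lower), and with only the others it was 1840. With only the suffixed arrays the calls of Ahsa1, Dnajb1, Hspb8, Xbp1, Psmd10, Gadd45a and Ndufa2 were lost, with only the others that of Tm7sf2, and with either those of Gjb6, Pcna, B2m, Isg20, Ndufs7 and Sc5d. The calls of Cyp51, B2m and Ndufs7 were lost in the fit of 2 groups, that of B2m with the mean over its probe sets and that of Isg20 with array weights. Camera called 15 of the 22 lists, 13 with an estimated correlation, and some of these lists share genes. In the 18 splits of these 8 arrays that put 2 of each group on either side, 0 to 5 lists were called. The fry test also called 15, with the p53 and apoptosis list, higher (adjusted p = 0.0207), in place of the interferon list (adjusted p = 0.132). A sign of RNA quality, the 3' minus 5' difference of beta-actin, was 2.31 ± 0.2 in Htt171-82Q and 2.48 ± 0.13 in Htt171-19Q (exact permutation p = 0.2, two-sided, 0.55 adjusted over 12 tests). That of GAPDH was 0.595 ± 0.31 and 0.652 ± 0.12 (exact permutation p = 0.8, two-sided, 0.982 adjusted). On GAPDH, Htt171-82Q replicate 1 stood at 1.05 and the other arrays of its group at 0.35 to 0.55.

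The comparisons with GFP and with uninfected cultures set the long-repeat fragment against virus alone and against no virus. Against GFP, Sst fell by 2.54 ± 0.13, Htr2c fell by 2.46, Npy fell by 2.35, Enc1 fell by 2.33 and Arpp21 fell by 2.26, while Gpnmb rose by 2.23 ± 0.22, Cp by 2.06, Vim by 1.79, Hspb1 by 1.71 and Hopx by 1.64. Against uninfected cultures, Plcxd3 fell by 2.62, Htr2c fell by 2.60, Npy fell by 2.52 and Enc1 fell by 2.51, while Gpnmb rose by 2.83, Cp by 2.11, Aldh1a1 by 2.08, Hopx by 1.65 and Efhd1 by 1.61. In both comparisons the other probe sets of Htr2c (-0.13 and -0.07) and Enc1 (0.20 and -0.01) were not called. Transthyretin (Ttr) fell by 3.36 ± 0.83 against uninfected (adjusted p = 0.00746), with an SD of 1.74 over the Htt171-82Q arrays. Ttr was also at 6.16 ± 0.5 in the 3 GFP arrays, all below the uninfected ones at 8.9 ± 0.41. The difference of -2.73 ± 0.88 was not called (limma adjusted p = 1). Its SE comes from the fit over all 14 arrays, where the Htt171-82Q and Htt171-19Q arrays spread most (SD 1.74 and 1.59). The missing call thus does not show that Ttr was alike in GFP and uninfected arrays. Ttr was not called in Htt171-82Q against GFP (-0.63 ± 0.83, limma adjusted p = 0.621). Beta-actin's 3' minus 5' difference was 2.6 ± 0.11 in GFP and 2.71 ± 0.098 in uninfected arrays, against 2.31 ± 0.2 in Htt171-82Q (exact permutation p = 0.0571 and 0.0286, two-sided, the smallest possible being 0.0286, and 0.228 for both adjusted over 12 tests). The mean of 27 bacterial control probe sets was 3.66 ± 0.0245 (SD) over the 8 Htt171 arrays and 3.56 ± 0.0209 over the 6 control arrays (exact permutation p = 0.000333, two-sided). Against GFP 3726 probe sets were called, 2044 higher (54.9%) and 1682 lower, and against uninfected 4040, 2223 higher and 1817 lower. A fit of only the 2 groups compared called 2669 against GFP (50.1% higher) and 3049 against uninfected (50.8% higher). Without GFP replicate 1 the count against GFP was 2473, with 1208 higher and 1265 lower (48.8% higher), and with each array centred on its median 66.8% of the calls were higher. No control array carries the title suffix. The Htt171-82Q arrays without it gave 3413 calls against GFP and 3968 against uninfected, and those with it 4019 in each. In both comparisons 14 lists were called, 11 with an estimated correlation, and these 14 were also called against Htt171-19Q in the same direction. Immediate early genes were not called against GFP (camera adjusted p = 0.0734) or uninfected (0.151), with medians of 0.0249 and 0.0135 and camera's direction downward. Fry called them lower in both (adjusted p = 0.0047 and 0.00763), and p53 and apoptosis genes higher in both (0.00194 and 1.44e-05). It also called proliferation genes (0.0229) and astrocyte markers (0.0125) higher against GFP and oligodendrocyte markers lower against uninfected (0.0447), and did not call the interferon list against uninfected (0.066). Camera also called the immediate early list lower against GFP without GFP replicate 2 (adjusted p = 0.0438) or Htt171-82Q replicate 2 (0.0222), with array weights (0.0394), with the title suffix as a covariate (0.0397) and without the suffixed arrays (0.0249), and in both comparisons without dim probe sets (0.00339 and 0.0169). The interferon list was lost in both without Htt171-82Q replicate 1 (0.106 and 0.33), without dim probe sets (0.182 and 0.325), with the suffix as a covariate (0.0504 and 0.0994) and without the suffixed arrays (0.121 and 0.358). Against uninfected, oligodendrocyte markers (camera adjusted p = 0.0683) were called lower without uninfected replicate 2 (0.0209) or Htt171-82Q replicate 1 (0.0442) or 2 (0.0348), with the suffix as a covariate (0.0179) and without the suffixed arrays (0.0107). Respiratory chain genes (0.273) were called higher in the last 2 settings (0.0457 and 0.0275). The heat shock list against GFP (adjusted p = 0.071 with an estimated correlation), the glutamate list against uninfected (adjusted p = 0.0545 with an estimated correlation), and the proteasome and interferon lists in both were lost with an estimated correlation (adjusted p = 0.147 and 0.458 with an estimated correlation against GFP, 0.16 and 0.507 against uninfected).

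A set of 1575 probe sets differed in Htt171-82Q from all 3 other groups in one direction, 724 higher and 851 lower, with 16 and 99 at least 2-fold in each. They made up 73.3% of the calls against Htt171-19Q. With each comparison fitted on its own 2 groups, the set held 1080, 417 higher and 663 lower (38.6% higher). The fit over all arrays shares 1 spread per probe set between groups. Yet differences between arrays had SDs of 0.2097 to 0.2798 within Htt171-82Q, against 0.1421 to 0.1454 within GFP and 0.1344 to 0.1477 within uninfected. The 3 comparisons share the Htt171-82Q arrays, so overlap arises without any effect in common. In 20 simulations without effects the highest overlap was 0, which does not bear on overlap between comparisons that hold effects. Independent lists of these sizes would share 32.4. When the Htt171-82Q arrays were split, 2 against Htt171-19Q and the other 2 against GFP, the 6 such splits shared 910 to 1120 calls, and independent lists of the sizes in each split would share 110 to 241. With all arrays these 2 comparisons shared 1684, and independent lists would share 252. With only the suffixed Htt171 arrays and all controls, the set held 976, of which 34.6% were higher, against 46% with all arrays. With each array centred on its median more were higher than lower, 894 against 798, as without Htt171-82Q replicate 2, 936 against 820.

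The fragment with 19 glutamines was likewise set against virus alone and against no virus. Against GFP, the phosphatase gene Phlpp1 rose by 0.79 ± 0.11 (adjusted p = 0.00196), the transporter gene Slc13a3 by 0.66, the retinaldehyde-oxidizing enzyme gene Aldh1a1 by 0.64, Sst by 0.54 and Bphl by 0.53. Gosr1 fell by 1.56 ± 0.31 (adjusted p = 0.0195), Rasa1 fell by 1.01, Pacsin1 fell by 0.91, the mineralocorticoid receptor gene Nr3c2 fell by 0.74 and Mgat2 fell by 0.69. Other probe sets of Gosr1 (-0.14) and Pacsin1 (0.06) were not called. In total 504 probe sets were called, 325 higher (64.5%) and 179 lower, of which 68.7% had a mean below the median level. The bacterial control probe sets, at 3.66 in the Htt171 arrays and 3.56 in the control arrays, differed in this comparison too. The share of higher calls was 76.6% with each array centred on its median, 46.7% (28 higher and 32 lower) without dim probe sets, 50.3% (672 and 663) with only the suffixed Htt171 arrays and 52.3% without GFP replicate 2. The count dropped to 60 without dim probe sets, to 206 with the title suffix as a covariate and to 162 without the arrays that carry it, and was 1335 with only those Htt171 arrays. It was 86 without GFP replicate 1 and 86 without GFP replicate 2, 151 without GFP replicate 3, 328 without Htt171-19Q replicate 1, 140 without its replicate 3, 186 without its replicate 4, 331 without uninfected replicate 3 and 872 without Htt171-82Q replicate 2. The calls of Sst, Bphl, Rasa1, Pacsin1 and Gosr1 were each lost without GFP replicate 1, 2 or 3 and without Htt171-19Q replicate 3 or 4. That of Bphl was also lost without Htt171-19Q replicate 1, that of Rasa1 without any 1 uninfected array, that of Aldh1a1 without GFP replicate 3 and that of Mgat2 without GFP replicate 2. For Sst, Bphl, Rasa1, Pacsin1, Gosr1, Aldh1a1 and Mgat2 the highest adjusted p over the alternatives was 0.138, 0.126, 0.166, 0.144, 0.087, 0.0578 and 0.0684. The calls of Sst, Bphl and Rasa1 were also lost with the title suffix as a covariate and without the suffixed arrays, those of Sst, Bphl, Rasa1 and Pacsin1 without dim probe sets, that of Sst in the fit of 2 groups and that of Rasa1 with trend and robust variances. By camera no list was called, with 2 at an unadjusted p under 0.05, and fry called none. With the suffix as a covariate camera called 3, the striatal projection neuron list, lower (adjusted p = 0.000903), the GABA list, lower (0.0447), and the respiratory chain, higher (0.00858). The striatal and GABA lists, both at an adjusted p of 0.06 with all arrays, were called lower without GFP replicate 2 (0.028 for both) or Htt171-19Q replicate 4 (0.0337 for both) and with each array centred on its median (0.0457 for both). The GABA list alone was called without GFP replicate 3 (0.0116) or Htt171-19Q replicate 2 (0.0343) and with quantile normalization (0.0449), and the striatal list alone without Htt171-19Q replicate 3 (0.0307) and without the suffixed arrays (0.0029).

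Against uninfected cultures, Htt171-19Q showed higher Aldh1a1, by 1.58 ± 0.12 (adjusted p = 8.78e-06), Gpnmb, by 1.34, Htra1, by 1.10, Igfbp2, by 0.90, and the heme oxygenase gene Hmox1, by 0.84. Ttr fell by 3.31 ± 0.83 (adjusted p = 0.032, at most 0.144 over the alternatives), Gosr1 fell by 1.57, the GABA-synthesizing enzyme gene Gad2 fell by 1.14, Pcdha13 fell by 1.05 and the myelin gene Mbp fell by 1.02. Ttr was not called against GFP (-0.58 ± 0.83, limma adjusted p = 0.729), where it was at 6.16. Other probe sets of Gosr1 (0.07) and Mbp (0.10) were not called. Of 872 called probe sets, 515 were higher (59.1%) and 357 lower. The share of higher calls was 50.4% without dim probe sets, 51.3% without the suffixed arrays and 50.9% with only the suffixed Htt171 arrays. With quantile normalization it was 52.9%, and with each array centred on its median 64.1%. The count was 347 without dim probe sets, 540 without the suffixed arrays and 1341 with only those Htt171 arrays. It was 244, 360 and 291 without uninfected replicates 1, 2 and 3, and 431 and 494 without Htt171-19Q replicates 3 and 4. The call of Ttr was lost without any 1 uninfected array or without Htt171-19Q replicate 2, 3 or 4, that of Gosr1 without uninfected replicate 2 or 3, and that of Gad2 without uninfected replicate 1 or 2 or Htt171-19Q replicate 3 or 4. The calls of Ttr, Gad2 and Foxp1 were also lost without the suffixed arrays, those of Ttr and Foxp1 with the suffix as a covariate and that of Ttr with trend and robust variances. For Gosr1 and Gad2 the highest adjusted p over the alternatives was 0.0558 and 0.0983. By camera the striatal projection neuron list alone was called, with 2 falls among 35, Ptpn5 (fell by 0.45) and Foxp1 (fell by 0.53), or 6 adjusted over the list alone (camera adjusted p = 0.00603; adjusted p = 0.406 with an estimated correlation). Fry did not call it (adjusted p = 0.122) and called 2 others, the unfolded protein response (0.00205) and p53 and apoptosis genes (0.00631), both higher. The call of Ptpn5 was lost without uninfected replicate 1 or 3, and that of Foxp1 without any 1 uninfected array or Htt171-19Q replicate 3 or 4 (adjusted p at most 0.0646 and 0.145). The striatal call was lost without Htt171-19Q replicate 2 (adjusted p = 0.0709) and with only the suffixed Htt171 arrays (0.337). Respiratory chain genes (0.185 with all arrays) were called higher without uninfected replicate 2 (0.025) or Htt171-19Q replicate 4 (0.0254), without dim probe sets (0.0132), with the suffix as a covariate (0.000894) and without the suffixed arrays (0.0367). Oligodendrocyte markers (0.227) were called lower without uninfected replicate 2 (0.0412) and with that covariate (0.0214). Beta-actin's 3' minus 5' difference was 2.48 ± 0.13 in Htt171-19Q and 2.71 ± 0.098 in uninfected arrays (exact permutation p = 0.0571, two-sided, 0.228 adjusted over 12 tests).

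Infection with the GFP virus left 2 probe sets called against uninfected cultures, and 515 at an unadjusted p under 0.05. Aldh1a1 rose by 0.94 ± 0.13 (limma adjusted p = 0.0149) and Tcap, which encodes a sarcomere protein, fell by 0.84 ± 0.09 (adjusted p = 0.00389). Without uninfected replicate 1 or 2 the count was 0, and without uninfected replicate 3 or GFP replicate 2 it was 1. It was 6 without Htt171-82Q replicate 2 or 3, 5 without its replicate 4, and 22 in a fit of these 2 groups alone. The call of Aldh1a1 was lost without any 1 uninfected array or GFP replicate 1 or 2, and that of Tcap without uninfected replicate 1 or 2. Over the alternatives the adjusted p of Aldh1a1 reached 0.169 and that of Tcap 0.0572. The next genes by p-value did not pass: Hmox1 at 0.62 (adjusted p = 0.0734), Paqr8 at 0.46, Tp53inp2 at 0.38, Igfbp7 at 0.48, Angptl4 at -0.55 (adjusted p = 0.0531), Igsf1 at -0.68, the peptide gene Cartpt at -0.78 and Minar2 at -0.45. Other probe sets gave -0.03 for Paqr8 and -0.09 for Igsf1. All 8 passed with array weights, and some without 1 array: Angptl4 and Hmox1 without Htt171-82Q replicate 2, 3 or 4, Angptl4 also without Htt171-19Q replicate 2, Cartpt without Htt171-82Q replicate 2 or 4, Igsf1 and Tp53inp2 without Htt171-82Q replicate 3, and Igfbp7 without GFP replicate 1. By camera 4 lists passed with no member called, also adjusted over the list alone. These were p53 and apoptosis genes, higher (adjusted p = 0.00619), the unfolded protein response, higher (0.0422), oligodendrocyte markers, lower (0.00619), and proliferation genes, lower (0.0422). None passed with an estimated correlation (adjusted p = 0.0788, 0.127, 0.219 and 0.557 with an estimated correlation) or by fry (adjusted p = 0.0551, 0.0551, 0.331 and 0.806). Camera called 1 list without GFP replicate 1, and 2 without GFP replicate 3, uninfected replicate 3 or Htt171-82Q replicate 1 or 2. The p53 list was lost without GFP replicate 1 (adjusted p = 0.0772), without dim probe sets (0.0799) and with the mean over a gene's probe sets (0.0973), and oligodendrocyte markers without uninfected replicate 1 (0.0693). The unfolded protein response was lost without any 1 GFP array, uninfected replicate 1 or 3 or Htt171-82Q replicate 1 or 2 (at most 0.189). Proliferation genes were lost without uninfected replicate 2 or 3, GFP replicate 1 or 3 or Htt171-82Q replicate 1 or 2 (at most 0.225). Both were also lost with quantile normalization (0.0629 for both), without dim probe sets (0.0902 and 0.361) and in the fit of 2 groups (0.0508 for both). Heat shock genes were called higher without uninfected replicate 1 (0.0425), respiratory chain genes higher without uninfected replicate 2 (0.0404), astrocyte markers lower without GFP replicate 2 (0.0365) and synaptic vesicle genes lower without dim probe sets (0.0444). The myelin gene Mbp was at -0.59 ± 0.18 and the cell cycle inhibitor gene Cdkn1a at 0.27 ± 0.09, neither called, with other probe sets at 0.06 and -0.09.

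Rat Htt was measured by 2 probe sets, which need not detect the human fragment and so do not check the labels. Probe set 1370395_at was 6.95 ± 0.13 in Htt171-82Q, 6.85 ± 0.13 in Htt171-19Q, 6.86 ± 0.05 in GFP and 6.89 ± 0.03 in uninfected arrays. Probe set 1371569_at was 7.23 ± 0.11, 7.03 ± 0.02, 7.23 ± 0.09 and 7.28 ± 0.1 in the same order. No comparison passed, the smallest adjusted p being 0.0556 for Htt171-19Q against uninfected.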

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

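The tests of an equal loss of all neurons, of bacterial control probe sets and of the splits by how many arrays they exchange were chosen only after the results were seen. Of 254 group values tested for 1 array far from the other 3, 15 stood apart. Chance marks about 1 in 20 groups, or about 13 here.

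Striatal projection neuron genes were lower in Htt171-82Q than in Htt171-19Q. An equal loss of all neurons as the whole cause would lower pan-neuronal genes alike. Of the 24 pan-neuronal genes, 17 (70.8%) had 95% intervals above -0.654. This was the median of the 23 striatal genes above the median level (bright), and was taken as fixed. The pan-neuronal median was -0.25. Over all 35 measured striatal genes the median was -0.246, so the medians differed only among bright genes. The means over all measured genes were -0.59 for the striatal and -0.34 for the pan-neuronal list. Members of each list differed widely, and the difference of the medians among bright genes did not pass a permutation test (p = 0.107, two-sided). That test shuffles genes between the lists and asks only whether their medians differ. An equal loss as the whole cause also forbids a wide spread within a list. Bright pan-neuronal genes ran from -1.15 ± 0.12 (SE, Nefl) to 0.46 ± 0.1 (Uchl1), with an SD of 0.388 over genes. Bright striatal genes had an SD of 0.732. With the 17 intervals above the striatal median, these values argue against an equal loss as the whole cause, for bright genes. A loss of part of the neurons, or of some kinds, stays open. Against a batch marked by the title suffix, 95.7% of the 23 bright striatal genes were lower both within the arrays that carry it and within the others, with medians of -0.556 and -0.696. An effect of the longer repeat, which the design names, stays open and is a hypothesis.

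Calls of Htt171-19Q against GFP lay mostly among dim probe sets. Outside the tested probe sets, 27 bacterial control probe sets near the floor were higher by 0.101 in the 8 Htt171 arrays, 3.66 ± 0.0245 (SD) against 3.56 ± 0.0209 in the 6 others (exact permutation p = 0.000333, the smallest that 3003 splits can give, two-sided). The Htt171 arrays all lay above the others, and 239 of the 346 dim calls were higher, which is consistent with a background or batch difference of the Htt171 arrays. Quantile normalization kept 71.6% of the calls, which falls between the bounds set for a distribution left by the scaling, so this cannot be told apart. No control array carries the title suffix, and an effect of the fragment stays open, untested.

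Ttr, a transcript of choroid plexus and other cells, differed widely between arrays of one Htt171 group. In Htt171-82Q it was 8.14 in replicate 4 and 4.58 to 4.77 in the others, a gap of 0.945 of the range, and in Htt171-19Q 7.92 in replicate 1 and 4.57 to 5.26 in the others. Choroid plexus RNA in some cultures cannot be told apart: 14 other choroid genes had a median within-group correlation of 0.0758 with Ttr, at the 91.17th percentile of random lists, but only Aqp1, at 6.79, and Igf2, at 6.44, lay above the median level. On the title suffix as the cause, arrays with it (4.77 and 4.58) and without it (4.65 and 8.14) overlapped in Htt171-82Q. By the rule set beforehand this speaks against the suffix. In Htt171-19Q, however, both arrays with it (4.58 and 4.57) lay below those without it (7.92 and 5.26). Ttr was also lower with it on average over the 2 groups (-1.87), so a part played by the suffix is not excluded. In GFP, which carries no fragment, Ttr was at 5.78 to 6.73, below the 8.47 to 9.28 of uninfected arrays, and no biological explanation was tested.

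The other arrays that stood apart are given as the gap divided by the group's range. In Htt171-82Q these were Atf3 in replicate 2 (0.942), Cdk1 in replicate 2 (0.856), Bid in replicate 3 (0.835), Igsf1 in replicate 3 (0.961), Ndufa2 in replicate 3 (0.872), Gabrb2 in replicate 4 (0.949) and Ramp2 in replicate 4 (0.837). In Htt171-19Q they were Atp2a2 in replicate 1 (0.915), Bcas1 in replicate 1 (0.837), Bid in replicate 1 (0.838), Kcnc2 in replicate 2 (0.87), Cnp in replicate 3 (0.852), Pcdha13 in replicate 3 (0.878) and Plcb1 in replicate 4 (0.856).

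Other splits of the same arrays were run for each count. For probe sets, only 1 of 35 splits, the real one, gave as many calls in 5 comparisons. This is the smallest share that 35 splits can give, and it was not adjusted over comparisons that share arrays. Splits that mix the groups widen the spread within them, which by itself lowers their counts. Against GFP or uninfected, the splits cannot tell infection with a fragment from the array difference seen on the bacterial control probe sets. The real count and the highest other were 2148 and 161 for Htt171-82Q against Htt171-19Q, 3726 and 2110 against GFP, 4040 and 1658 against uninfected, 504 and 11 for Htt171-19Q against GFP, and 872 and 23 against uninfected. The split with 161 follows the title suffix. For the set that differs from all 3 other groups, 1 of 100 regroupings gave 1575 and the highest other 0. For gene lists this share does not exclude chance: 4 of 35 splits gave at least the 15 lists of Htt171-82Q against Htt171-19Q (highest other 17), 8 of 35 at least 14 against GFP (16) and 8 of 35 at least 14 against uninfected (18). Those highest splits kept 3 of the 4 Htt171-82Q arrays together and so hold much of the real contrast, and all 3 other splits with at least 15 for Htt171-82Q against Htt171-19Q exchanged only 1 array. In the 18 splits that exchanged 2 arrays, the counts were 0 to 5 for that comparison, so there the share over all splits says little about chance. In the 18 such splits each against GFP and uninfected, no probe set was called. Yet the list counts were 1 to 14 against GFP, where 1 split reached the real count, and 0 to 12 against uninfected. With 4 against 3 arrays, these splits divide the Htt171-82Q arrays unevenly and so still hold part of the real contrast. For the lists of these 2 comparisons they therefore cannot decide on chance, which is neither excluded nor shown. For Htt171-19Q against GFP the real count was 0, which all 35 splits reach by construction, so they say nothing about chance there (highest other 3). Against uninfected 19 of 35 gave at least 1 (highest other 4). The 10 splits of GFP and uninfected arrays are too few for a share under 0.05: the real split gave 2 probe sets and 4 lists, the highest other 0 and 3, and 1 split reached the real value in each.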

How the results depend on the processing

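Leaving out the 4 arrays with the title suffix, or the other 4 Htt171 arrays, was chosen after seeing the data. Of 155 values of the 127 genes that the rule took, 116 kept direction and side of the threshold under every alternative. These include values never called, such as those of list members in GFP against uninfected, so the count does not measure the stability of calls alone. Sc5d reversed with the mean over its probe sets (0.075), where its probe sets oppose. Causes below were not tested unless the setting has fewer arrays or probe sets. Quantile normalization gave 1 list for Htt171-19Q against GFP and 2 for GFP against uninfected, and median centring 2 for the former. Median centring gave 66.8% higher calls for Htt171-82Q against GFP (54.9% as deposited) and 76.6% for Htt171-19Q against GFP (64.5%), and both scalings 33.3% of 3 calls for GFP against uninfected (50%). Without dim probe sets, Htt171-19Q had 60 probe sets against GFP and 347 with 2 lists against uninfected, and GFP had 2 lists. Too few microglia and endothelial genes were left for a test there. Fitting only the 2 groups gave 1374 for Htt171-82Q against Htt171-19Q, and 22 with 2 lists for GFP. Trend and robust variances gave 5 for GFP. Array weights gave 1259 and 1865 for Htt171-19Q against GFP and uninfected, and 21 for GFP. The title suffix as a covariate gave 206 with 3 lists for Htt171-19Q against GFP, 3 lists against uninfected, and 10 for GFP. An estimated correlation left 0 lists for Htt171-19Q against uninfected and 0 for GFP. Fry gave 2 for the former, neither of them the list called by camera, and 0 for GFP.

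Without the suffixed arrays, Htt171-19Q gave 162 with 1 list against GFP and 540 with 2 lists against uninfected, and GFP 9. Without the other 4, Htt171-82Q against Htt171-19Q gave 1185 and against all 3 groups 976, Htt171-19Q 1335 against GFP and 1341 with 0 lists against uninfected, and GFP 10. Leaving out each array in turn gave probe set counts of 1707 to 2602 for Htt171-82Q against Htt171-19Q, 2473 to 3930 against GFP, 2917 to 4097 against uninfected and 1319 to 1756 against all 3, and 86 to 872, 244 to 1178 and 0 to 6 for the other 3 comparisons. List counts ran from 14 to 16, 13 to 15, 14 to 15, 0 to 2, 0 to 3 and 1 to 4. Pseudocounts were not run because the values are already on a log scale. No paired analysis was possible because the titles of any 2 groups share at most 1 number. Signal near the floor limits what dim probe sets can show.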

Other observations

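The tests below were fixed before their results were seen. Other members of the striatal list, chosen after their values were seen, moved unequally between Htt171-82Q and Htt171-19Q. The dopamine signalling phosphoprotein gene Ppp1r1b fell by 1.5 ± 0.11 (SE, limma adjusted p = 1.65e-07), Pde10a fell by 0.95, the dopamine receptor gene Drd1 fell by 0.94 and the cannabinoid receptor gene Cnr1 fell by 0.70, each on its brightest probe set. Other probe sets of Pde10a (-0.44), Drd1 (-0.12) and Cnr1 (-0.16) were not called. Drd2 was at -0.02 ± 0.11 and Rgs9 at -0.11 ± 0.08, neither called, and Drd1 and Drd2 lay below the median level of all probe sets in each group. The adenosine receptor gene Adora2a was at -0.06 on its brightest probe set, not called, and fell by 0.38 on its other one (adjusted p = 0.00666). The transcription factor gene Foxp1 fell by 0.78.

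The large falls of Sst and Npy may come from a loss of the interneurons that express both. Of 5 other genes of these cells, 3 were measured, with a median of -0.211, and only Nxph1, which fell by 1.06 ± 0.12 (adjusted p = 1.45e-05), lay above the median level. Tacr1 was at -0.21 and Nos1 at 0.07, neither called, so the test leaves the question open.

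The rises of Cp, Vim, Gfap and Hspb1 may belong to a reactive astrocyte gene programme. The 17 other measured genes of that list, named before the test, had a median of 0.0183 and did not pass as a set (camera with an estimated correlation, p = 0.382). Of these, Timp1 (0.86), Serping1 (0.78), S100a10 (0.67) and S1pr3 (0.54) rose and Amigo2 fell by 1.01, so members moved in both directions and the test leaves this open too. Several of the 17 were dim in Htt171-19Q, such as Srgn at 3.77, Serpina3n at 4.33 and Lcn2 at 4.55, which limits the test.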
